A study of Mus musculus with 16 samples.

How the data were processed

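Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of BRD4, a bromodomain protein that binds acetylated histones, was done on cardiac myocytes of 4 control mice and 4 mice in which the lamin A/C gene Lmna was deleted in myocytes with a Myh6-driven Cre recombinase, called knockout (KO) below. Each of the 8 ChIP samples had an input sample. The 8 input samples were not analysed here.

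The authors deposited 1 table of genome intervals per genotype, in which each interval carries the count of libraries with a peak there and their names, per the file headers. Reads were trimmed with Trim Galore, aligned with Bowtie2 2.3.4.3 and searched for peaks with MACS2 2.1.1 on genome build mm10, per the submitters' processing notes. The peak-calling threshold is not given in the sources used here. The deposited values hold the presence or absence of a peak, with no read count, height or score, so that sequencing depth is unknown and the number of peaks cannot be adjusted for it. A library sequenced more deeply, or with a stronger immunoprecipitation, gives more and wider peaks at equal occupancy.

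The control table names libraries ChIP-1 to ChIP-4 and the KO table ChIP-5 to ChIP-8. These names do not match the numbers in the sample titles, so each library was used as an unnumbered replicate of its genotype. In the control table, 10 chromosomes (10 to 19) stood in 2 separate blocks, with ChIP-1 in a block of its own. Peaks were therefore rebuilt per library from the names, by joining touching intervals. The peak list of a genotype was the union of its 4 libraries, merged with bedtools 2.31.1 at a minimum overlap of 1 bp. The union of both lists gave regions that were shared, control-only or KO-only.

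Gene positions came from a RefSeq gene table of the same build with 21887 protein-coding genes on the assembled chromosomes. The table gives neither strand nor exons, and no genome sequence was used. The planned window around the transcription start was replaced by 2 kb on either side of both annotated gene ends, and the planned classes exon and intron by inside a gene. A gene is called marked when a peak overlaps that window. Peak bases were also summed over the gene body with 5 kb on either side. Motif searches and the alternative with the start sites of every transcript were not run.

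Library measures were compared with an exact two-sided permutation test, 4 libraries against 4, whose smallest possible p is 0.0286. Nothing in the files gives the batch or day of a library. Overlap of the lists was compared with 1000 circular shifts of the KO list within each chromosome, one-sided. The 19 gene lists were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 19 lists. Genes are not independent replicates, so these p-values describe a list of peaks and carry no error between mice. Each count was also set among 10000 random lists matched on decile of gene length. Wilson 95% intervals cover counting error only. The odds ratios within single libraries have 95% intervals from the log odds, and their p-values were adjusted over 160 tests, 20 lists (the 19 and the fatty acid and sarcomere lists joined) in 8 libraries. Peaks within 12 kb of each other were stitched, and groups of at least 5 peaks were counted as clusters. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

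The gene lists, the overlap test, the list tests on the control list and on genes marked in 1 genotype only, the window sizes and the rule for named genes were set before the data were examined. The use of both gene ends, the flank on both sides of the gene body and the tests between libraries, for which the plan had none, were chosen once the contents of the tables were known. The lists covered sarcomere, cardiac transcription factors, ion channels and calcium handling, cardiac stress and fetal genes, oxidative phosphorylation, fatty acid and energy metabolism, extracellular matrix, TGF-beta and EMT, TNF and NF-kB inflammation, E2F and cell cycle, p53 and DNA damage response, FOXO factors and targets, BET proteins and transcription elongation, nuclear lamina and envelope, markers of fibroblasts, endothelium, macrophages and leukocytes, and smooth muscle and pericytes, genes of other lineages, and housekeeping genes. The rule named the genes with the widest shared, KO-only and control-only regions at a gene end, those with the most genotype-only bases, up to 4 members per list with the largest difference in peak bases, and Lmna, Brd4, Myh6, Nppa and Nppb. Other genes were chosen after their values were seen. So were the list tests within single libraries, on the KO list as a whole, on the control-only share of genes marked in 1 list and on genes in 2 or more libraries, and the requirement of support from 2 libraries.

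The steps were tested on simulated data. For the overlap of lists, 499 of 500 planted overlaps were found among 7872 simulated peaks, and 2 of 100 pairs of unrelated lists of 8000 peaks passed the threshold of 0.05. These peaks were placed at random along the chromosomes, so this rate does not cover lists that lean to gene ends. For gene marking, 200 of 200 planted genes among 21887 were found. For the list test, 195 of 200 planted lists with 70% of members marked were called, and a list was called in 6 of 200 simulations without a planted one. The alternatives were other windows, overlap rules, widths, list sizes, stitching distances and cluster sizes, and the omission of each library in turn.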

Results

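BRD4 peaks were compared between cardiac myocytes of control mice and of mice lacking lamin A/C in myocytes, with 4 ChIP libraries per genotype. Lamin A/C forms part of the lamina under the nuclear envelope, and its loss in the heart causes dilated cardiomyopathy and arrhythmia. The study's title names inhibition of BRD4 as a treatment in this model, and the comparison asks where BRD4 lies in each genotype. Each value below is the presence, width or number of peaks, since the tables hold no read depth.

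The deleted gene, Lmna (chromosome 3, 88481148 to 88509932, mm10), had a peak at a gene end in 1 of 4 control libraries and 2 of 4 KO libraries. Within the gene body and 5 kb on either side, peaks covered 1249 bp in the control list and 1250 bp in the KO list. A BRD4 peak near the Lmna ends does not report the deletion of exons, so these values do not check the genotype labels. Brd4 itself (chromosome 17, 32196272 to 32284743) was marked in 1 control and 2 KO libraries, by 578 bp and 773 bp of peaks. The natriuretic peptide gene Nppa had no peak in any of the 8 libraries, and Nppb had 59 bp of peaks in 1 control library.

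The libraries differed widely in how many peaks they held. The control libraries had 816, 4804, 7874 and 462 peaks (ChIP-1 to ChIP-4), and the KO libraries 17460, 2576, 1129 and 27 (ChIP-5 to ChIP-8). The means were 3489 ± 3524 in control and 5298 ± 8175 in KO (SD, n = 4 each; exact permutation p = 0.83, two-sided). None of 8 library measures passed the test, which included covered length, median width and the shares of peaks on the X chromosome, on the Y chromosome and at gene ends (exact permutation, lowest unadjusted exact p = 0.229, all adjusted exact p = 0.886). The 4 libraries with the most peaks marked 2778 and 3621 genes in control and 8207 and 1531 in KO, whereas ChIP-4, ChIP-7 and ChIP-8 marked 40, 34 and 3 genes. In ChIP-7 the median peak was 46 bp wide, and 89.3% of its peaks were under 60 bp.

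**Figure D1:**
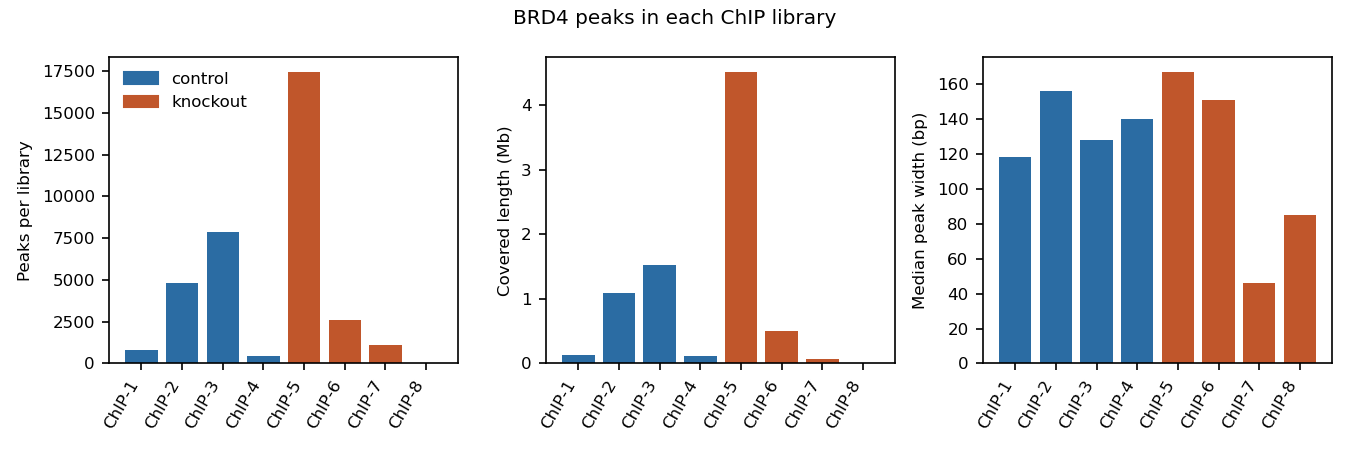
Bars give, for each ChIP library, the number of peaks, the covered length in Mb and the median peak width in bp, with control libraries in blue and KO libraries in orange. ChIP-5 held 17460 peaks over 4.52 Mb, and ChIP-8 held 27 peaks.

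The widest region at a gene end that both genotypes shared, 4094 bp, lay on chromosome 17 (34118738 to 34122831) over an end of Brd2, which encodes another BET protein, and an end of the overlapping antigen-presentation gene H2-DMa. Regions of 2989 bp at the AP-1 gene Jun (chromosome 4, 95050323 to 95053311), 2886 bp at Klf13 and 2638 bp at Bhlhe40 followed, with 2464 bp at Jund, an interval that the neighbouring gene Iqcn also took in, and 2128 bp at Zbtb1. Brd2 and Jun were each marked in 3 control and 2 KO libraries. A further AP-1 gene, Fos, had 2517 bp of peaks in control and 1754 bp in KO, Junb 3161 bp and 1264 bp, and the stress factor Atf3 2154 bp and 1068 bp, while Jund had 1861 bp and 2557 bp and the leucine zipper gene Cebpb 908 bp and 1796 bp.

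Of 24830 regions in all, 4310 were shared, 6461 were control-only and 14059 were KO-only. A KO peak overlapped 43.4% of the 11416 control peaks, 4955 peaks against a mean of 106 in 1000 shifted lists (permutation p = 0.001, one-sided, the smallest that 1000 shifts can give). A shift moves peaks away from gene ends, so 2 lists that merely favour gene ends could pass too. The test thus cannot separate common BRD4 sites from a common leaning to such places. A control peak overlapped 24.1% of the 18520 KO peaks, and the bases in both lists made up a Jaccard index of 0.203. Shared regions had a median width of 525.5 bp, against 82 bp for control-only and 115 bp for KO-only regions. A shared region joins the overlapping peaks of both lists, and wide peaks overlap more easily, so part of this difference is built in. ChIP-5 alone held 86.9% of the KO-only regions, and ChIP-3 alone 64.5% of the control-only regions. Without ChIP-5, the KO list was 0.320 times as long as the control list, instead of 1.62 times, and 14.2% of control peaks overlapped a KO peak. Without ChIP-3 the ratio was 3.38.

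Shared regions lay mostly at gene ends. Of those on assembled chromosomes, 70.8% had their place within 2 kb of a gene end (Wilson 95% interval 69.5% to 72.2%), 15.7% inside a gene and 13.5% between genes, while such windows take up 5.48% of these chromosomes. For control-only regions the share at gene ends was 30.5% (29.4% to 31.6%) and for KO-only regions 39.3% (38.5% to 40.1%). The order was the reverse for regions in 2 or more libraries of 1 genotype and 0 of the other. There it was 44.6% of 193 control regions (37.7% to 51.6%) and 18.7% of 1107 KO regions (16.5% to 21.1%). Of these KO regions, 873 were narrow ones of ChIP-5 and ChIP-7 alone, with 2.75% at gene ends. The widest KO-only regions at the ends of protein-coding genes were 1463 bp between Dpm1 and Mocs3 (chromosome 2), 1407 bp at Fbxw7 (chromosome 3), 1302 bp at Nmi, 1174 bp at Tent4b, 1169 bp at Ptprj and Gm46752, 1151 bp at Ppp2r5e, 1150 bp at Lemd2 and 1140 bp at Nanos1. Each of these 8 regions came from 1 library, ChIP-5. A wider KO-only region, 1972 bp, lay inside Unc45b, which encodes a myosin chaperone. Without ChIP-5, the share of KO-only regions at gene ends was 26.3%.

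At the level of genes, 4010 genes were marked in both lists, 870 only in the control list and 4333 only in the KO list, of 21887 tested. The control-only region with the greatest width at a gene end, 1034 bp on chromosome 11, lay at Kdm6b, which encodes a histone H3 lysine 27 demethylase, and Dnah2. It was followed by 820 bp at Myh6, 811 bp at Hspb8, 725 bp at Polr3gl, 686 bp between Plxdc1 and Arl5c and 650 bp at the clock gene Per1. The regions at Kdm6b, Myh6, Hspb8, Polr3gl and Arl5c were each found in 2 control libraries, and that at Per1 in 3. By other peaks, the ends of Kdm6b and Per1 were also marked in 2 KO libraries, and those of Myh6 and Hspb8 in 1. Dnah2, Polr3gl, Plxdc1 and Arl5c were marked in no KO library. The region at Myh6 lies within the neighbouring gene Cmtm5. Genes marked in 2 or more control libraries and no KO library numbered 95, and the opposite 235. Among the 95 were the contractile genes Tcap and Tnni3, the myoglobin gene Mb, the small heat shock protein gene Hspb6 and Lpl, and among the 235 were Sun1, Ryr2, Atp5b and Nr2f6. No gene was marked in 4 libraries of one genotype and none of the other. ChIP-4, ChIP-7 and ChIP-8 marked only 40, 34 and 3 genes, so such a gene was hardly possible and its absence says nothing about the genotypes. Without ChIP-5, 302 genes were marked only in the KO list. With support from 2 or more libraries required in each list, the number was 684. Under that rule a gene with a peak in only 1 control library can count as KO-only, which the 235 genes above exclude.

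In the control list, genes of heart function were marked more often than other genes. The other genes were all remaining protein-coding genes, expressed or not. Expression was not measured, so this difference, here and for the lists below, cannot be told apart from expression in myocytes. Of the fatty acid and energy metabolism list, 21 of 28 genes were marked (75% against 22.2% of other genes, odds ratio 10.5, Fisher's exact test, adjusted exact p = 8.45e-08), among them Plin5 (1604 bp of peaks), Fabp3 (588 bp) and Hadhb (525 bp). The sarcomere list had 18 of 30 marked (odds ratio 5.24, adjusted exact p = 3.53e-05), with 5924 bp of peaks at Myh6, 951 bp at Myh7 and 801 bp at Tcap. Cardiac transcription factors had 15 of 24 (odds ratio 5.82, adjusted exact p = 8.39e-05), with 1716 bp at Mef2d and 1247 bp at Srf. Cardiac stress and fetal genes had 10 of 20 marked (adjusted exact p = 0.0126), ion channels and calcium handling 13 of 31 (adjusted exact p = 0.0290) and oxidative phosphorylation 12 of 29 (adjusted exact p = 0.0360). Without ChIP-3 these last 3 lists did not pass (adjusted exact p = 0.0739, 0.322 and 0.0802 in this order), nor did cardiac transcription factors (adjusted exact p = 0.0648), and without ChIP-2 stress genes (adjusted exact p = 0.111) and oxidative phosphorylation (adjusted exact p = 0.691) did not. Over all alternatives the adjusted exact p reached 0.478 for stress genes, 0.449 for ion channels and 1 for oxidative phosphorylation.

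Regulatory lists were also marked more often in the control list. FOXO factors and targets, which act in atrophy and autophagy, had 20 of 27 marked (odds ratio 9.99, adjusted exact p = 1.43e-07), nuclear lamina and envelope genes 15 of 20 (odds ratio 10.5, adjusted exact p = 3.77e-06), and BET proteins and transcription elongation 17 of 24 (odds ratio 8.49, adjusted exact p = 3.44e-06). TNF and NF-kB inflammation had 15 of 32 (odds ratio 3.08, adjusted exact p = 0.00578), p53 and DNA damage response 13 of 32 (adjusted exact p = 0.0318) and housekeeping genes 9 of 16 (adjusted exact p = 0.00780). Fibroblast markers had 0 of 16 marked, as had macrophage and leukocyte markers, both less often than other genes (adjusted exact p = 0.0425 each). Extracellular matrix genes (8 of 34, adjusted exact p = 0.884), E2F and cell cycle genes (7 of 33, adjusted exact p = 1), endothelial markers (7 of 16, adjusted exact p = 0.0712), smooth muscle and pericyte markers (0 of 14, adjusted exact p = 0.0636) and genes of other lineages (1 of 20, adjusted exact p = 0.0712) did not pass. Without ChIP-3, 8 lists passed, against 14 in all. The fibroblast and macrophage lists did not pass without ChIP-3 (adjusted exact p = 0.302 each) or without ChIP-2 (adjusted exact p = 0.134 each).

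**Figure D2:**
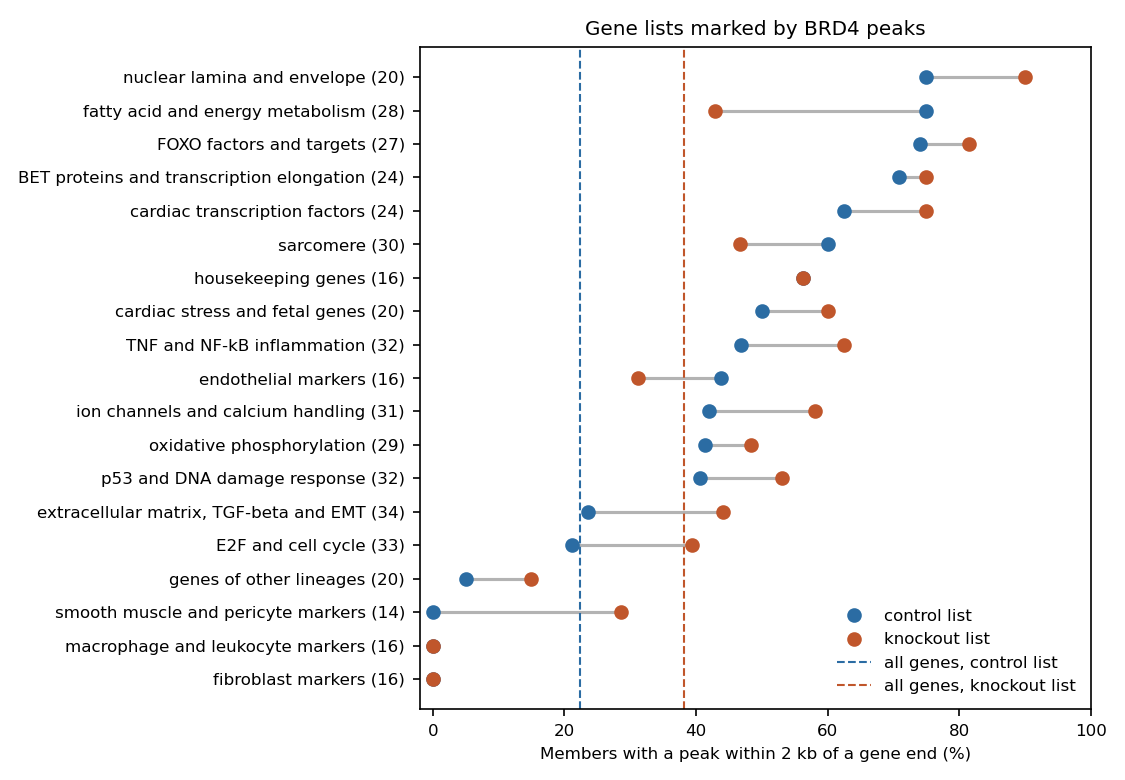
Each point gives the percentage of a list's members with a peak within 2 kb of a gene end, in the control list (blue) and the KO list (orange), and dashed lines give the percentages over all genes. Fatty acid and energy metabolism stood at 75% in control and 42.9% in KO, and nuclear lamina and envelope at 75% and 90.0%.

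The KO list was longer and marked 38.1% of all genes, 8343, of which ChIP-5 marked 8207. Against that level, nuclear lamina and envelope genes (18 of 20, adjusted exact p = 4.22e-05), FOXO factors and targets (22 of 27, adjusted exact p = 7.03e-05), cardiac transcription factors (18 of 24, adjusted exact p = 0.00167), BET proteins and transcription elongation (18 of 24, adjusted exact p = 0.00167) and TNF and NF-kB inflammation (20 of 32, adjusted exact p = 0.0158) were marked more often than other genes by Fisher's exact test. Fibroblast markers and macrophage and leukocyte markers, with 0 of 16 each, were marked less often (adjusted exact p = 0.00167 each). Of the lists that passed in control, 7 did not pass here. Sarcomere had 14 of 30 marked (odds ratio 1.42, against 5.24 in control, adjusted exact p = 0.476) and fatty acid and energy metabolism 12 of 28 (1.22 against 10.5, adjusted exact p = 0.780). Ion channels and calcium handling had 18 of 31 (2.25 against 2.52, unadjusted exact p = 0.0262, adjusted 0.0623), cardiac stress and fetal genes 12 of 20 (2.44 against 3.49, adjusted 0.119) and p53 and DNA damage response 17 of 32 (1.84 against 2.39, adjusted 0.173). Housekeeping genes had 9 of 16 (2.09 against 4.49, adjusted exact p = 0.310) and oxidative phosphorylation 14 of 29 (1.52 against 2.46, adjusted exact p = 0.378). Among random lists matched on gene length, the KO count lay at percentile 99.2 for stress genes, 96.1 for p53, 95.7 for housekeeping, 95.6 for oxidative phosphorylation, 91.5 for ion channels, 70.2 for sarcomere and 62.7 for fatty acid genes. A list that passed in control and not in KO is not thereby shown to differ. Tests on genes marked in 1 list only follow below. Smooth muscle and pericyte markers had 4 of 14 marked, each by ChIP-5 and by no other library, among them Abcc9, Mylk and Notch3 (adjusted exact p = 0.698), and endothelial markers 5 of 16 (adjusted exact p = 0.842). Extracellular matrix genes (15 of 34, adjusted exact p = 0.612), E2F and cell cycle genes (13 of 33, 0.860) and genes of other lineages (3 of 20, 0.0788) did not pass in either list. Peaks covered 1702 bp in KO and 89 bp in control at Foxo1, 1774 bp and 761 bp at Foxo3, 1150 bp and 0 bp at Lemd2, 1309 bp and 256 bp at Sun1, and 815 bp and 55 bp at Lmnb1. At the potassium channel gene Kcnh2 they covered 1716 bp and 229 bp, at Kcnb1 1566 bp and 179 bp, and at the ryanodine receptor gene Ryr2 637 bp and 0 bp. Foxo3, Sun1, Ryr2 and Kcnb1 were marked in 2 KO libraries, ChIP-5 and ChIP-6, and Lemd2, Foxo1, Lmnb1 and Kcnh2 in 1, ChIP-5. At the ends of Foxo3, Sun1, Ryr2 and Kcnb1, ChIP-6 covered 76, 119, 175 and 224 bp, against 1774, 590, 637 and 1518 bp in ChIP-5. All these genes were named for their large difference in bases. The whole KO list covered 4.73 Mb, against 2.27 Mb in control.

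No list passed adjustment among genes marked only in the KO list. The nuclear lamina and envelope list had the lowest p, with 4 of its 5 genes not marked in control (Lemd2, Nup98, Sun1 and Syne2) marked in KO (Fisher's exact test, p = 0.0168, adjusted exact p = 0.111), and 3 of 19 lists were under 0.05 without adjustment. Without ChIP-3, 4 lists passed, namely nuclear lamina and envelope (9 of 11, adjusted exact p = 0.00746), cardiac transcription factors (12 of 17, adjusted exact p = 0.00746) and, with 0 of 16 each, the fibroblast and macrophage markers. Without ChIP-2, 3 lists passed, nuclear lamina and envelope (8 of 9, adjusted exact p = 0.00636) and the same marker lists. Cardiac transcription factor genes marked in KO alone were Nkx2-5, Hand2, Tbx20, Meis1 and Esrrg, each by ChIP-5.

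No list passed adjustment among genes marked only in the control list either. Of the 21 fatty acid and energy metabolism genes marked in control, 9 were not marked in KO: Hadha and Hadhb, which share 1 locus, and Ech1, Lpl, Cpt1b, Pdk2, Pdk4, Ucp3 and Ckm (Fisher's exact test, p = 0.00662, adjusted exact p = 0.126). Of 18 sarcomere genes marked in control, 6 were not marked in KO: Ttn, Tcap, Tnni3, Ldb3, Myoz2 and Cryab (adjusted exact p = 0.434). A gene not marked may still hold peaks away from its ends, as Tcap did with 48 bp in KO. Under 0.05 without adjustment were 2 of 19 lists, fatty acid and energy metabolism and E2F and cell cycle. The latter had 4 of 7 genes control-only (57.1% against 17.8% of other genes, Fisher's exact test, p = 0.0223, adjusted exact p = 0.212). Without ChIP-6, fatty acid and energy metabolism (12 of 21, adjusted exact p = 0.00238) and sarcomere (9 of 18, adjusted exact p = 0.0299) passed, both more often control-only than other genes. Without ChIP-5 the direction turned: sarcomere genes (8 of 18, 44.4% against 74.3% of other genes, adjusted exact p = 0.108) and fatty acid genes (12 of 21, 57.1% against 74.3%, adjusted exact p = 0.261) stood below other genes without passing, and TNF and NF-kB inflammation genes were control-only less often (5 of 15 against 74.3%, adjusted exact p = 0.0195).

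Among the genes marked in 1 list only, fatty acid genes stood on the control side. All 9 of the list were control-only, against 16.6% of other such genes (Fisher's exact test, adjusted exact p = 1.88e-06), and with Hadha and Hadhb counted once it was 8 of 8 (adjusted exact p = 1.12e-05). Of 8 sarcomere genes 6 were control-only (adjusted exact p = 0.00422), and Xirp1 and Actn2 were KO-only. These shares also depend on how many genes could become KO-only. Those not marked in control were 7 of 28 fatty acid genes and 12 of 30 sarcomere genes, but 17000 of 21859 genes outside the fatty acid list. The tests above within genes marked, or not marked, in control avoid this, and fatty acid genes did not pass them (Fisher's exact test, adjusted exact p = 0.126 and 0.629). A high control-only share is therefore no proof of a loss in KO. The other 17 lists did not pass. Among them, endothelial markers had 3 of 4 control-only (Cdh5, Esam and Tie1), with an odds ratio of 15.0 as for sarcomere genes (exact p = 0.0163, adjusted exact p = 0.103). Without ChIP-5, neither list passed (adjusted exact p = 1 for both), and the log2 odds ratio was 1.07 instead of 6.58 for fatty acid genes and 0.51 instead of 3.70 for sarcomere genes. Without ChIP-2, sarcomere did not pass (adjusted exact p = 0.186), at a log2 odds ratio of 3.05. Over all alternatives the adjusted exact p ranged from 2.10e-08 to 1 for fatty acid genes and from 7.14e-05 to 1 for sarcomere genes.

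Within single libraries, the KO libraries ChIP-5 and ChIP-6 gave different values for these genes. The odds ratio of the fatty acid list was 5.18 in ChIP-2, 9.12 in ChIP-3 and 6.33 in ChIP-6 (95% interval 2.86 to 14), and 0.789 in ChIP-5 (0.357 to 1.75). For the sarcomere list it was 6.91, 4.43, 6.69 (3.12 to 14.3) and 0.965 (0.459 to 2.03) in the same order. For cardiac transcription factors, ChIP-5 had 5.01 and ChIP-6 3.51. For ion channels and calcium handling the odds ratio was 4.64 in ChIP-6 (2.07 to 10.4, exact p = 0.00594 after adjustment over 160 tests) and 2.31 in ChIP-5 (1.13 to 4.72, adjusted exact p = 0.0958). For cardiac stress and fetal genes it was 5.72 (2.19 to 14.9, adjusted exact p = 0.0102) and 1.67 (0.694 to 4.01, adjusted exact p = 0.640). The difference between these 2 libraries was not tested. Over the 8 libraries, the lowest unadjusted p for a list's share of the marked genes was 0.0857, for housekeeping genes (exact permutation test). With 19 lists and 4 libraries against 4, no single list could pass adjustment in this test whatever its values, and ChIP-4, ChIP-7 and ChIP-8 marked 40, 34 and 3 genes.

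**Figure D3:**
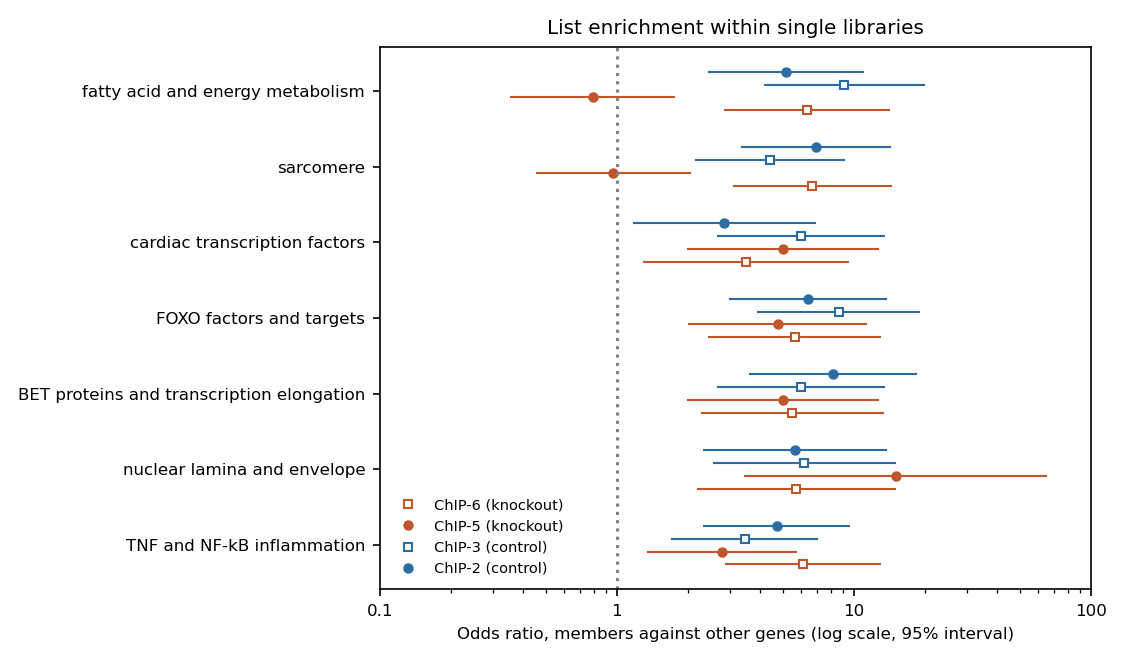
Points give the odds ratio, on a log scale, that a list member rather than another gene had a peak within 2 kb of a gene end, with 95% intervals, in the 4 libraries with the most peaks. ChIP-5 lay at 0.789 for fatty acid and energy metabolism and at 0.965 for sarcomere, and the other 3 libraries lay above 4 for both.

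**Figure D4:**
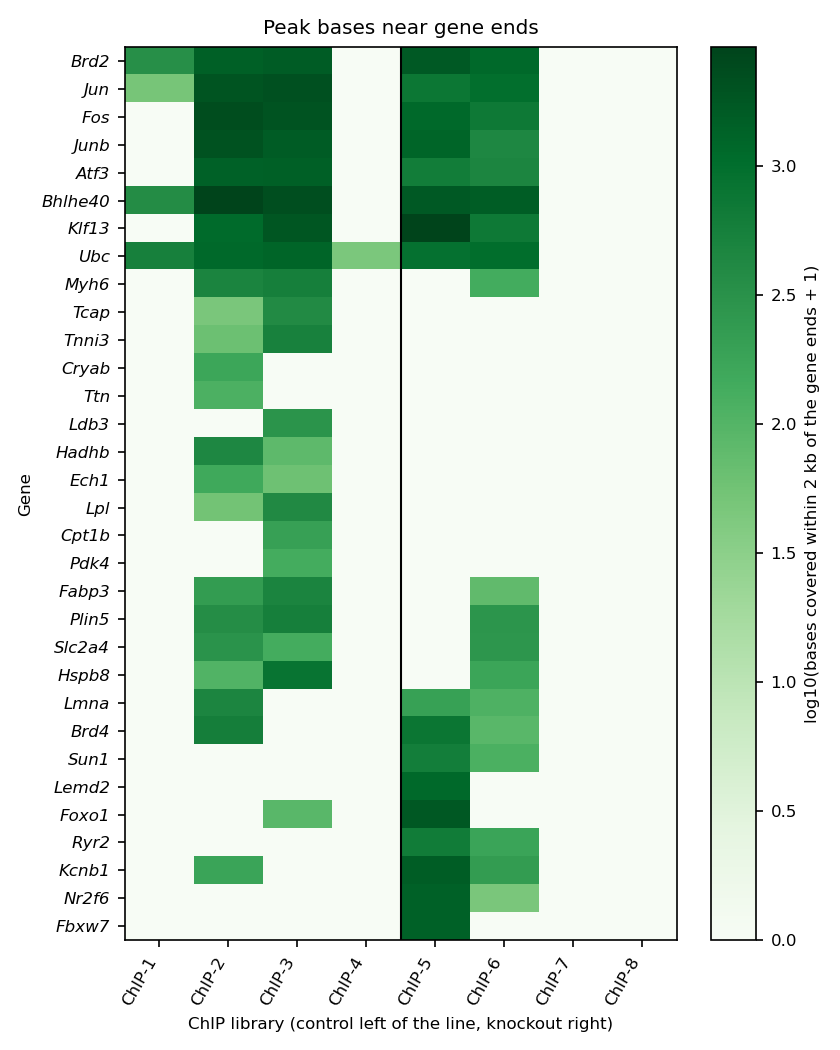
Colour gives log10 of the bases covered by peaks within 2 kb of the gene ends, plus 1, for 32 genes in each library. Ech1, Lpl and Tcap were covered in ChIP-2 and ChIP-3 and in no KO library, whereas Fabp3, Plin5 and Slc2a4 were also covered in ChIP-6.

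The Myh6 locus, which encodes the alpha myosin heavy chain of the adult mouse heart, showed the largest difference in peak bases among sarcomere genes. Peaks over Myh6 (chromosome 14, 54941921 to 54968017) and 5 kb on either side covered 5924 bp in the control list and 875 bp in the KO list. The KO peaks there came from ChIP-6. In the control list, 20 peaks formed a cluster from 54936200 to 54968217 that covered 6645 bp and took in Cmtm5. ChIP-5, the library with the most peaks, had no peak there. The Cre transgene of the KO mice carries the Myh6 promoter, and the files give no way to set its copies apart.

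**Figure D5:**
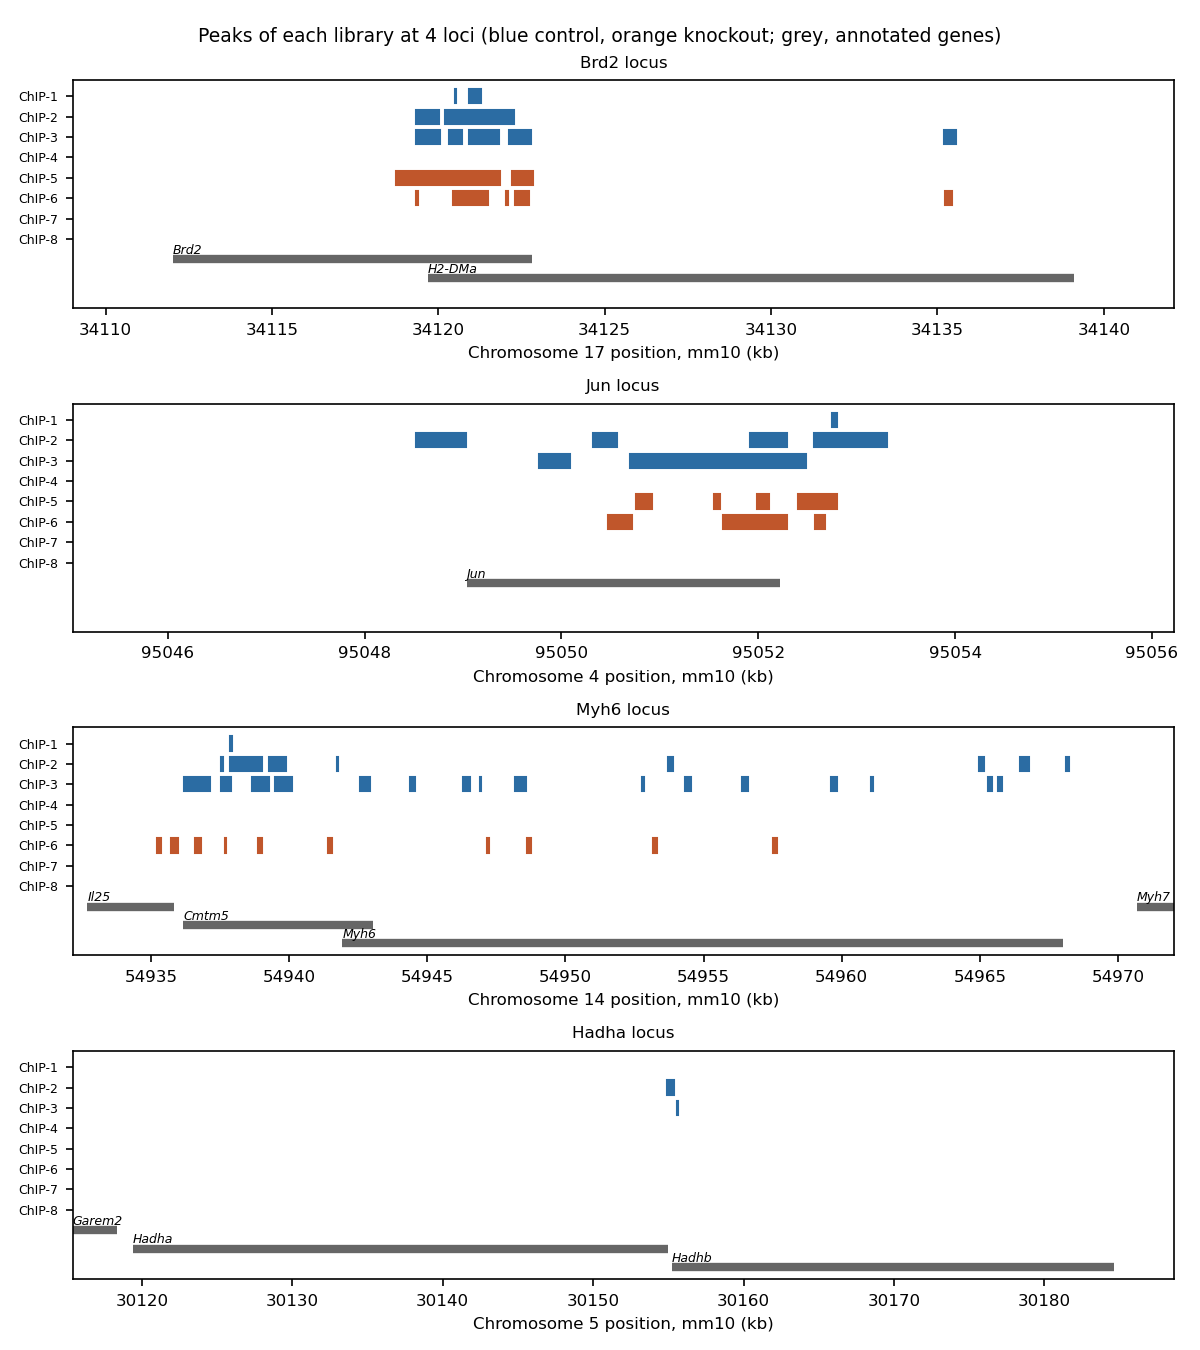
Coloured boxes are peaks of each library (control blue, KO orange) against position on mm10 in kb, and grey bars are annotated genes. At Brd2 and Jun both ChIP-5 and ChIP-6 had peaks, at Myh6 only ChIP-6 among the KO libraries, and at Hadha and Hadhb none of them.

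Stitching gave 116 clusters in the control list and 99 in the KO list, and 39 control clusters overlapped a KO cluster. The cluster with the most peaks in both lists lay over Sfi1 on chromosome 11, with 68 control and 61 KO peaks, and the longest lay on an unplaced sequence (114391 bp and 114115 bp). Others found in both lists lay over Mid1 on the X chromosome, on further unplaced sequences and near the end of the Y chromosome. Neither the input nor repeats were examined, so it is not known whether these clusters reflect BRD4 or a signal that input shows too. Kdm6b lay in a control cluster of 15 peaks that covered 4622 bp. Without ChIP-2 or ChIP-3 the ratio of KO to control clusters, 0.853, was 2.02 and 1.90, and without ChIP-5 or ChIP-6 it was 0.224 and 0.560. With the KO list reduced to the size of the control list, it held 46 clusters.

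On the X chromosome, 85.4% of 869 regions were KO-only (Wilson 95% interval 82.9% to 87.6%), against 55.4% on the autosomes (54.8% to 56%), and on the Y chromosome 81.8% of 325 (77.3% to 85.7%). Narrow regions shared by ChIP-5 and ChIP-7 alone (median 55 bp) made up 129 of 266 KO-only regions on Y and 88 of 742 on X. Control peaks numbered 0.754 per Mb on X and 4.50 per Mb on the autosomes, and KO peaks 4.66 and 6.99. X-linked genes with more KO bases included Bcor (3494 bp against 705 bp), Med14 (945 bp against 201 bp) and Fhl1 (887 bp against 0 bp). The ends of each were marked in 1 KO library, ChIP-5. Those of Bcor and Med14 were also marked in 1 control library, ChIP-2. Without ChIP-5 the KO-only share on X was 45.3%. The test between genotypes on the library shares of peaks on X was not passed (1.61% ± 1.89 against 3.68% ± 4.08, SD, n = 4 each; exact permutation p = 0.429).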

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

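In this part, the tests of the narrow regions at gene ends and by shifting, of ChIP-5, of short peaks, of genotype, of other cells and with ChIP-5 reduced to as many marked genes as ChIP-3 were chosen after the results they measure had been seen. The tests with ChIP-5 reduced to as many peaks as ChIP-3, of other splits and of the sex chromosomes were set before.

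Among the KO libraries, ChIP-5 stood far above the others, with 17460 peaks and 4.52 Mb covered, each with a gap to the next library of more than the critical share of the range. Of 18 groups of values examined, 2 were singled out in this way, and chance singles out about 1 in 20. Without ChIP-5 the ratio of KO to control peaks was 0.320, and without ChIP-3, the control library with the most peaks, 3.38, which restates their size and leaves open whether 1 library accounts for the larger KO list. Short peaks as the source of the larger KO list are argued against, since with peaks of at least 200 bp alone the ratio was 2.19. This value does not bear on the part of ChIP-5. An effect of genotype on peak number stays open, because 4 libraries with this spread gave an exact permutation p of 0.83.

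The weaker marking of fatty acid and sarcomere genes in the KO list may come from ChIP-5 and not from the genotype: in ChIP-6 the odds ratio of both lists joined was 6.55, against 6.04 in ChIP-2, 6.26 in ChIP-3 and 0.877 in ChIP-5. The larger number of calls in ChIP-5 is argued against, since with its 7874 widest peaks, as many as ChIP-3 holds, the odds ratio was 1.10 (95% interval 0.627 to 1.95), and with its 4069 widest peaks, which mark 3621 genes as ChIP-3 does, 1.05 (0.531 to 2.08), both below the lower bound of 3.72 in ChIP-3. Keeping the widest peaks does not reproduce a shallower library, so sequencing depth stays open. For chromatin of fibroblasts or leukocytes, 0 of 32 marker genes were marked in ChIP-5 (0%), against 37.6% of other genes (Fisher's exact test, p = 3.56e-07). Both marker lists had 0 members marked in every other library too. No library thus shows that they would detect such cells, and this explanation stays open. Of the 35 splits of the 8 libraries into 4 and 4, 10 separated the joined lists from other genes as strongly (log2 4.97, highest other split 5.21), but these are the 10 that keep ChIP-2 and ChIP-3 apart from ChIP-5, so the count follows those 3 libraries and chance is not excluded. For smooth muscle and pericyte cells, 4 of 14 markers were marked in ChIP-5 and 0 in each other library. In ChIP-5 this was 28.6% against 37.5% of other genes (odds ratio 0.667, Fisher's exact test, unadjusted p = 0.589). The markers thus did not stand above other genes, and this explanation stays open. Antibody performance, sample handling and a wrong label of ChIP-5 were not tested.

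ChIP-5 and ChIP-7 shared 873 narrow regions, median 55 bp, that no other library had. Coincidence is argued against, as 956 peaks of ChIP-7 overlapped ChIP-5 and the highest of 100 shifted lists gave 13. Copy number of X and Y cannot be the whole cause, since 75.1% of the regions lay on autosomes (95% interval 72.2% to 77.9%). BRD4 sites at gene ends are argued against too, with 2.75% at gene ends, against 80.3% of the 228 regions on assembled chromosomes that ChIP-5 and ChIP-6 alone shared. What the regions are stays open, since repeats could not be examined without a genome sequence, and no biological explanation was tested.

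Genes marked in 2 or more libraries of one genotype and none of the other numbered 330, and 30 of the 35 splits gave as many (highest other 4041). Chance is therefore not excluded. The 5 splits that put ChIP-2, ChIP-3 and ChIP-5 together, the libraries with the most peaks, gave 2734 genes or more and the others 1754 or fewer, so the count follows the number of peaks, and no other structure of the samples was tested.

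Peaks outside the assembled chromosomes, which the gene comparisons do not use, numbered 186 on unplaced sequences in KO and 153 in control, and 2 on the mitochondrial genome in KO against 0 in control.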

How the results depend on the processing

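The requirement of support from 2 or more libraries and the list test on genes marked in 1 list only were chosen after the data had been seen. No paired analysis was possible because the library names carry no sample numbers. The replicate block, motif searches, start sites of every transcript and tests on read counts or peak scores were not run, for want of sample numbers, a genome sequence, strand and counts. Sequencing depth is unknown, so it cannot be said which missing peaks reflect low depth.

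Overlap of the lists stayed past its test in every alternative (100 shifts each), at 14.2% to 57% with a library left out. Fatty acid, sarcomere, FOXO, nuclear lamina, BET and TNF lists stayed past adjustment in the control list in all 14 alternatives. Calls were lost for fibroblast markers in 7 of 14, stress genes in 6, ion channels and macrophage markers in 5, p53 in 3, and cardiac transcription factors and housekeeping in 1 each (highest adjusted exact p = 0.478 for stress, 0.449 for ion channels). Oxidative phosphorylation lost its call in 3 with the direction kept. It lost it in 1 more, support from 2 libraries, where the log2 odds ratio reversed to -0.15. The cause was not tested.

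With a library left out, the ratio of KO to control peaks ranged from 0.320 to 3.38, the KO-only share at gene ends from 26.3% to 42.2%, KO-only genes from 302 to 5808, lists called in control from 8 to 14, in KO-only from 0 to 4, in control-only from 0 to 2 and among genes in 1 list only from 0 to 3, the ratio of clusters from 0.224 to 2.02 and the KO-only share on X from 45.3% to 90.9%. The cluster ratio was also above 1 without ChIP-3 (1.90). The cause was not tested.

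The KO-only share at gene ends was 34.1% with windows of 1 kb and 45.3% with 5 kb. With the KO list reduced to the control list's size, 2 lists were called in control-only, fatty acid (11 of 21) and endothelial markers (6 of 7), both more often than other genes, and the cluster ratio was 0.397. With the wider 50% of each list, 8 lists were called in control and 3 in KO-only. With support from 2 libraries, KO-only genes numbered 684, the KO-only share at gene ends was 36.2%, the cluster ratio 0.563, and lists called 8 in control, 1 in KO-only, 1 in control-only (TNF, 0 of 9, less often than the 51.2% of other genes) and 0 among genes in 1 list only. Under this rule a peak in only 1 library of the other genotype does not stop a gene from counting as genotype-only. The cause was not tested.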

Other observations

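The tests on genes in 2 or more libraries were chosen after the data had been seen. Chaperone and stress genes were among the 123 genes marked in 3 or more control and 2 or more KO libraries. They included the mitochondrial chaperonin pair Hspd1 and Hspe1, which share a promoter, Hspb1, Dnajb1, Hspa4, Hsp90ab1 and Stip1, with Atf4, Zfp36, Btg2, Keap1 and the polyubiquitin gene Ubc. Genes of heterogeneous nuclear ribonucleoproteins were in the same set: Hnrnpu, Hnrnpa3, Hnrnpa2b1, Hnrnph3, Hnrnpa0 and Hnrnpk. No list of either kind was fixed in advance, and no enrichment was tested. Ubc was the only gene of the fixed lists marked in 4 control libraries.

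Of the 11 fatty acid genes marked in 2 or more control libraries, 4 (Hadha, Hadhb, Ech1 and Lpl) had no KO mark, against 5.56% of other genes (Fisher's exact test, adjusted p = 0.0476). With Hadha and Hadhb counted once it was 3 of 10 and no longer passed (Fisher's exact test, adjusted p = 0.307). The housekeeping genes Gapdh and Rpl13a were likewise marked in 2 control and 0 KO libraries.

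The density of peaks on X relative to autosomes was 0, 0.187, 0.126 and 0.850 in ChIP-1 to ChIP-4 and 0.681, 0.186, 1.71 and 0 in ChIP-5 to ChIP-8. Over unplaced sequences, peaks covered 86542 bp in control and 110704 bp in KO. The widest shared region, 26793 bp on chromosome 9 from 3011508, lay near no gene and was found in 4 control and 2 KO libraries. Whether it stands out in the input as well was not examined.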
